A study of Mus musculus with 9 samples.

How the data were processed

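Gr-1+ cells of the spleen were isolated with magnetic beads on day 7 after bone marrow transplantation, and their RNA was hybridised to Illumina mouse BeadChips, which measure each transcript with probes on beads. Per the labels' protocols, RNA was used when the purity of the cells was above 97%. There were 3 groups of 3 arrays: cells of syngeneic hosts without graft-versus-host disease, of wild-type (WT) allogeneic hosts and of allogeneic hosts lacking IDO (KO). The syngeneic and WT arrays lay on 1 chip and the KO arrays on the other of 2 chips. Nothing in the labels says that the 3 arrays of a group came from separate animals, so the p-values measure only the spread between these arrays, which may be technical.

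The deposited table gives a signal intensity and a detection p-value for each of 45281 probes on each array. GenomeStudio is named in the submitters' processing notes; its version and settings are not given in the sources used here. The table is presented as not normalized, but its intensity values had been background-subtracted and quantile-normalized by the authors before deposit, as the values show: on each array the upper quartile was 102 and the highest signal 47219, and values reached down to -21.0. The deposited log2 values of the series matrix differed from log2 of these intensities by at most 1.1e-06, and they lack the 35.6% of signals at or below 0. Scale and direction of both tables are thus known, and no centring was found.

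The design, written before the data were examined, used the deposited detection p-values for the background model and the probe filter. In the deposited table these p-values followed the signals only in part. Each column's rank correlation with any signal column, p turned so that a low p ranks high, lay between 0.710 and 0.763. Of 10281 probes with a p of 0 in all 9 columns, 752 had a mean signal under 10, while of 3179 probes with signals over 1000 on every array 13 had a p over 0.05 in all columns. The normexp correction of limma with an offset of 50 and quantile normalization, which the design held ready for a table without detection p-values, was therefore used, and the fit as first designed was run as an alternative. The background limit was set after the data were seen, as the 95th percentile (signal 14.2) of 1594 probes for sensory receptor and keratin-associated genes; an earlier, lower limit was dropped because it let too many such probes pass. Probes above the limit on at least 3 of the 9 arrays were kept, 20782 in all.

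Gene names came from the platform annotation: 34885 probes have 1 symbol, 18 have several and 10378 are unnamed here. A gene identifier matched the reference for 34807 probes, and 0 symbols differed. The brightest passing probe stood for each of 10880 genes, of which 4253 had more than 1 passing probe. Among the other probes of the genes called, 22 of 145 had the opposite sign in KO vs WT, 77 of 761 in WT vs syngeneic and 115 of 858 in KO vs syngeneic.

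Log2 intensities were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 9 arrays and no covariate, moderated by eBayes, and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the scale of the offset intensities, which understates the change of dim genes. A gene not above the limit on any array of a group has only a bound there, given as "at least N-fold" against the group mean of the higher of the limit and the signal. Before the data were examined, 31 gene lists were fixed, with 461 member entries; 426 were on the array and 365 were tested. The 30 lists with at least 4 tested genes went through limma's camera with a preset correlation of 0.01. Camera with estimated correlation and fry were run beside it. Named genes were, by a rule also fixed then, the 10 largest rises and 10 largest falls (5 and 5 for KO vs syngeneic) among called genes whose groups did not overlap, without clone names and predicted genes, and up to 4 members of each list with the smallest p, besides Ido1, Ido2, Kmo and Kynu. Other list members that passed, and X-linked and Y-linked genes, are named as well, chosen after their values were seen.

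On simulated data with the spread of the 9 arrays and 200 changed genes among 10880, KO vs WT recovered 32.8% of changes of 0.5 on the log2 scale, 71.6% of changes of 1 and 92.4% of changes of 2, with 6 false calls. With the spread of the arrays without WT replicate 2, the shares were 76.1%, 98.5% and 100%, with 8 false calls. The raised simulated list was called in both, and 0 of 29 unchanged lists. Simulated genes varied independently, so these lists cannot show how often correlated members give false list calls. Each simulated gene also had the same spread on all arrays. In the data, log2 differences had an SD of 0.146 between WT replicates 1 and 3 and of 0.856 between 1 and 2. The recovered shares and false calls may thus differ in the data.

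Alternatives were no background correction, a median shift in place of quantile normalization, the series matrix values, other probe filters, the mean of a gene's probes, only the 6 arrays compared, an intensity trend with a robust prior, array weights, a replicate block, a fold threshold, and leaving out each array. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9. A probe's place relative to the disrupted part of Ido1 is not given in the sources used here, and a genome was not used here.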

Results

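The transcriptomes of splenic Gr-1+ cells, a population of neutrophils and related myeloid cells, were compared between 3 kinds of transplant hosts on day 7, to find pathways regulated by IDO1 in myeloid cells. IDO1 is the enzyme that starts the breakdown of tryptophan to kynurenine. Each group had 3 arrays. Between 19192 and 19221 probes lay above the background limit on each array, a near equality that the quantile normalization before deposit fixes. Arrays of the syngeneic group correlated with each other at a mean r of 0.998 over genes, and each KO array with the others of its group at a mean r of 0.993 to 0.995. WT replicate 2 stood apart. Its r with WT replicates 1 and 3 averaged 0.919, and the first principal component, with 48.4% of the variance, separated it from the other 8 arrays. Its T cell list lay 3.09 above WT replicates 1 and 3 on the log2 scale (median of 11 genes) and its erythroid list 3.42 above (12 genes). The difference for its mature neutrophil list was -2.74 (16 genes). Counts of changed genes, and of the members of lists that were called, are therefore also given without this array, a choice made after the data were seen.

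Ido1, the targeted gene, was dim on all arrays. Its signal was 7.6, 3.9 and 13.3 in syngeneic cells, 24.6, 33.8 and 20.0 in WT cells, and -2.3, 0.6 and -8.1 in KO cells. Thus 3 of 3 WT arrays and 0 of 3 arrays in each other group exceeded the limit of 14.2. Ido1 fell in KO vs WT by 0.55 ± 0.09 (log2 fold change ± SE, n = 3 arrays per group, adjusted p = 0.032), at least 1.15-fold. The call ended without each of syngeneic replicates 1, 2 and 3 (adjusted p = 0.0812, 0.074 and 0.0765), WT replicates 1 and 3 (0.0826 and 0.0678) and KO replicates 2 and 3 (0.104 and 0.139). It was also not called on the 6 arrays alone (0.203) or by the fit that used the deposited detection p-values (0.0546, log2 fold change -0.0045). It remained without WT replicate 2 (0.00326) or KO replicate 1 (0.0469). The log2 fold change was -1.38 without background correction (0.0251) and -1.01 with an offset of 16 in place of 50 (0.0246), both called. With KO signals below the limit, the size of these fold changes depends on how background is treated. The probe checks the labels only if it lies in the deleted part, which is not known here. Ido2, a related enzyme, and Kmo, which hydroxylates kynurenine, were too dim to test, with WT signals of 9.17 ± 8.38 and 0.10 ± 9.72 (SD, n = 3). Kynu, or kynureninase, had signals of 18.1 ± 2.29 in syngeneic, 49.2 ± 20.4 in WT and 51.8 ± 6.01 in KO cells. Its difference between KO and WT was 0.05 ± 0.13 on the log2 scale (adjusted p = 0.873). Of the 8 tested genes of the tryptophan-kynurenine pathway, 0 rose and 1 fell (Ido1) in KO vs WT, the same by limma adjusted over the list alone, and the list did not pass camera (adjusted p = 0.659). Without WT replicate 2, Qprt, which makes quinolinate into a NAD precursor, rose by 0.38 (adjusted p = 0.0175) and Wars, a tryptophan tRNA ligase induced by interferon-gamma, by 0.29 (adjusted p = 0.0246), against 0.26 and 0.19 with all arrays (adjusted p = 0.305 and 0.367), and the list was again not called (adjusted p = 0.844).

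KO vs WT asked which genes differ in Gr-1+ cells of allogeneic hosts with and without IDO1. Of 19 genes of the type I interferon response, which cells switch on after sensing virus or interferon, 7 rose in KO cells; the list passed camera with a preset correlation but not with an estimated correlation (adjusted p = 0.227). Isg15, a ubiquitin-like protein, rose by 1.53 ± 0.14 (log2 fold change ± SE, n = 3, adjusted p = 0.00413), and Irf7, a transcription factor that drives interferon production, by 1.77 ± 0.24 (adjusted p = 0.0144). Spic, a transcription factor that red pulp macrophages need and a member of no fixed list, rose by 2.41 ± 0.36 (adjusted p = 0.0222). C1qa, a chain of complement C1q, rose by 1.73 ± 0.30 (adjusted p = 0.0327) as 1 of the 2 of 12 monocyte and macrophage markers that passed. Xist, the RNA that coats the inactive X chromosome in female cells, fell at least 5.68-fold (adjusted p = 9.08e-05), from signals of 395 ± 61.3 to -8.25 ± 3.10 (SD, n = 3).

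Among the other largest rises in KO vs WT, Acot1, a thioesterase that splits fatty acyl-CoA, rose by 3.12 ± 0.36 (adjusted p = 0.00842), Plin2, a coat protein of lipid droplets, by 1.70 ± 0.31 (adjusted p = 0.0354) and Angptl4, an inhibitor of lipoprotein lipase, by 1.68 ± 0.30 (adjusted p = 0.0354). Tgm2, a transglutaminase, rose by 1.70 ± 0.09 (adjusted p = 0.000294) and Dab2, an endocytic adaptor, by 2.09 ± 0.16 (adjusted p = 0.00236). Amy2a5, a pancreatic amylase, rose by 2.46 ± 0.42 (adjusted p = 0.0302) and Ccl7, a chemokine that attracts monocytes, by 1.81 ± 0.28 (adjusted p = 0.0232). Among the falls, Kctd14 fell by 1.23 ± 0.15 and Upb1, an enzyme of pyrimidine breakdown, by 1.21 ± 0.24. Klf9, a transcription factor induced by glucocorticoids, fell by 1.13 ± 0.10 and Pdlim1, a cytoskeletal adaptor, by 1.06 ± 0.12. Ear6, a ribonuclease of the eosinophil-associated family, fell by 1.06 ± 0.21, and Ccl9, a chemokine, by 1.01 ± 0.18. Nfix, a transcription factor, fell by 1.01 ± 0.12, Fam174c by 0.98 ± 0.16 and Pdp2, a phosphatase that activates pyruvate dehydrogenase, by 0.97 ± 0.16. Adjusted p for these 9 falls lay between 0.00338 for Klf9 and 0.0493 for Ear6.

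**Figure D1:**
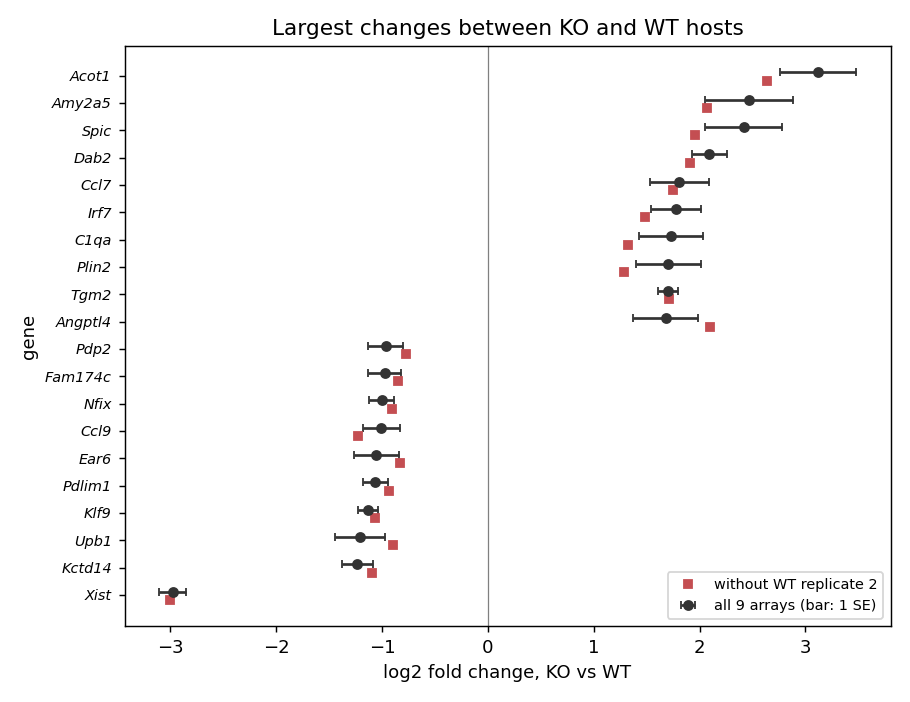
Log2 fold changes in KO vs WT (horizontal axis) of the 10 largest rises and 10 largest falls; black points use all 9 arrays with bars of 1 SE, and red squares leave out WT replicate 2. Each gene keeps its direction without that array, which the rule of non-overlapping groups fixes in advance. Values run from Acot1 at 3.12 with all arrays and 2.64 without WT replicate 2 to Xist at -2.98 and -3.01. Xist was below the background limit on all KO arrays, so the size of its change depends on the offset.

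Of 19 type I interferon genes tested in KO vs WT, 7 rose and 0 fell, and 18 rose adjusted over the list alone. The median was 0.94 (camera adjusted p = 2.74e-16, and adjusted p = 0.227 with an estimated correlation). All 3 KO arrays lay above all 3 WT arrays for 18 of the 19 genes. Chance gives 10% for separation in either direction, and of all genes tested 23.4% were separated in KO vs WT. Genes of 1 response on the same arrays are not independent. Usp18, which restrains interferon receptor signalling, rose by 1.29 ± 0.16, Oasl1 by 1.36 ± 0.13 and Stat2, a signal transducer of the interferon receptor, by 0.94 ± 0.11. Ifit2 rose by 1.45 ± 0.29 and Rsad2, or viperin, by 1.32 ± 0.23; both belong to the antiviral genes. WT replicate 2 lay below the mean of WT replicates 1 and 3 for all 19 genes. Without it 16 rose, with a median of 0.70. In the interferon-gamma response, 3 of 16 genes rose and 0 fell (7 and 1 adjusted over the list alone, 10 and 1 without WT replicate 2; camera adjusted p = 1.32e-05, and adjusted p = 0.189 with an estimated correlation). Cd274, the checkpoint ligand PD-L1, rose by 1.62 ± 0.22, Gbp2, a guanylate-binding GTPase, by 0.63 ± 0.10, and Icam1, an adhesion molecule, by 0.55 ± 0.11. In MHC class I presentation, Tap2, a subunit of the peptide transporter, rose by 0.61 ± 0.11 as 1 of 13 genes (6 adjusted over the list alone, 6 without WT replicate 2; camera adjusted p = 4.46e-05, and adjusted p = 0.155 with an estimated correlation).

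**Figure D2:**
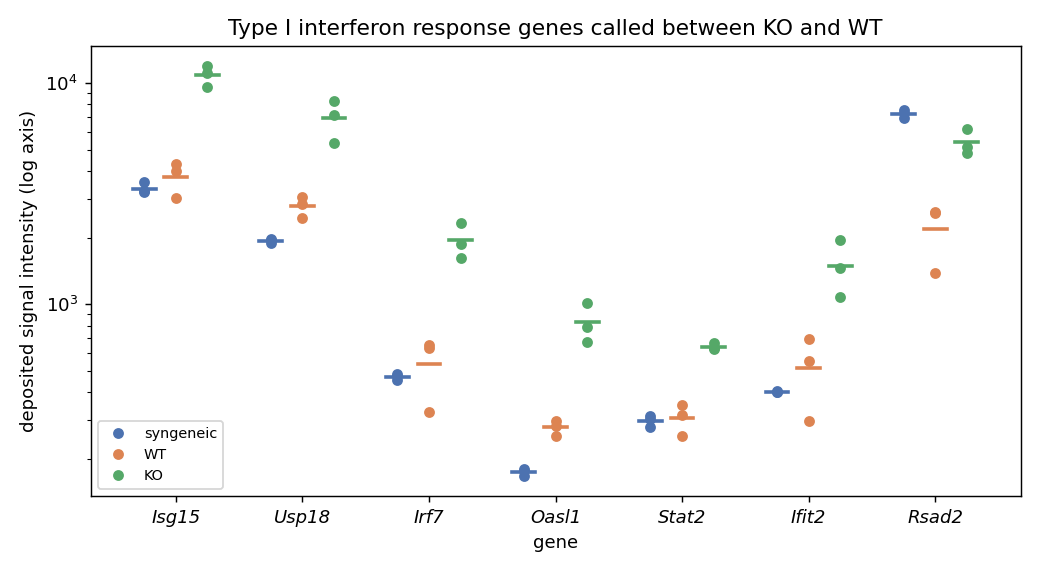
Deposited signal intensity (vertical log axis) of the 7 type I interferon genes that passed the test in KO vs WT; points are arrays, 3 per group, and lines are group means. For Isg15 the KO arrays sit between 9626 and 11890.3 and the WT arrays between 3011 and 4283.

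Monocyte and macrophage markers rose as a list in KO vs WT, with 2 of 12 genes rising (7 adjusted over the list alone) and a median of 0.96. The adjusted p was 2.92e-05, and adjusted p = 0.283 with an estimated correlation. WT replicate 2 lay below WT replicates 1 and 3 for this list (median -1.47), and without it the median was 0.63, with 6 rising and 1 falling (adjusted p = 2.56e-05, and adjusted p = 0.201 with an estimated correlation). Vcam1, an adhesion molecule of red pulp macrophages, rose by 1.21 ± 0.22. The mature neutrophil list was higher (1 of 16 rose, 2 adjusted over the list alone, 8 with 1 falling without WT replicate 2; camera adjusted p = 4.66e-05, and adjusted p = 0.499 with an estimated correlation). Ccrl2, a chemerin-binding receptor, rose by 0.70 ± 0.14. The secondary and tertiary granule list was higher with 0 of 13 genes rising, also adjusted over the list alone, and 0 at an unadjusted p under 0.05 in limma (camera adjusted p = 0.00445, and adjusted p = 0.624 with an estimated correlation). The median of the neutrophil and granule lists, 1.31 and 0.82, was 0.30 and 0.13 without WT replicate 2, where 1 granule gene rose and the granule list was not called (adjusted p = 0.259). The myeloid suppressor list rose (1 of 16, Cd274; 2 adjusted over the list alone, 5 with 1 falling without WT replicate 2; adjusted p = 0.00206, and adjusted p = 0.26 with an estimated correlation). In the amino acid starvation list, which rose, Trib3, a pseudokinase induced by ATF4, rose by 1.09 ± 0.16 as 1 of 16 genes (5 adjusted over the list alone, 4 without WT replicate 2; adjusted p = 0.0144, and adjusted p = 0.189 with an estimated correlation). Glycolysis (adjusted p = 0.00614, and adjusted p = 0.189 with an estimated correlation), antioxidant defence (0.0246, and adjusted p = 0.193 with an estimated correlation) and IL-6 and STAT3 signalling (0.0288, and adjusted p = 0.552 with an estimated correlation) rose as lists. Their members past the test in limma numbered 0 of 15, 0 of 19 and 0 of 16, also adjusted over the list alone, and 4, 3 and 4 had an unadjusted p under 0.05. Without WT replicate 2, 2, 4 and 4 of these genes rose, and 1 IL-6 and STAT3 gene fell. Without WT replicate 1 the starvation and antioxidant calls ended (both adjusted p = 0.0538). The antioxidant (0.0656) and IL-6 calls (0.566) ended without WT replicate 2, and the IL-6 call also without KO replicate 1 (0.0586), with array weights (0.533) and with the mean of a gene's probes (0.0561). Array weights ended the granule call too (0.428).

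G2 and M phase genes fell as a list in KO vs WT, with 0 of 11 falling, 6 adjusted over the list alone and 6 at an unadjusted p under 0.05 in limma (adjusted p = 0.00139, and adjusted p = 0.257 with an estimated correlation). Without WT replicate 2, 6 fell (adjusted p = 0.00523, and adjusted p = 0.293 with an estimated correlation). Erythroid markers fell as a list with 0 of 12 falling, also adjusted over the list alone, and 4 at an unadjusted p under 0.05 (adjusted p = 0.002, and adjusted p = 0.552 with an estimated correlation). WT replicate 2 had the high erythroid signals given above, and without it the median went from -1.61 to -0.31, with 3 of 12 falling (adjusted p = 0.0305, and adjusted p = 0.537 with an estimated correlation). Oxidative phosphorylation fell with 1 of 18 genes falling, also adjusted over the list alone, and 4 falling and 1 rising without WT replicate 2 (adjusted p = 0.0037, and adjusted p = 0.26 with an estimated correlation). Atp5o, an ATP synthase subunit, fell by 0.52 ± 0.07. Il1a, an inflammatory cytokine, rose by 0.96 ± 0.17 as 1 of 15 genes, also adjusted over the list alone, in the NF-kB cytokine list, which was not called (adjusted p = 0.058; 5 rose and 3 fell without WT replicate 2). The NF-kB list was called without WT replicate 1 (0.0248), WT replicate 3 (0.0283) or KO replicate 1 (0.0228). The fall of S phase genes was called without WT replicate 1 (0.0105), WT replicate 3 (0.0415) or KO replicate 3 (0.031). With all arrays and an estimated correlation, camera gave these lists an adjusted p of 0.552 and 0.649. The S phase median went from -0.20 to -0.002 without WT replicate 2 (adjusted p = 0.983). Other lists not called were S phase (adjusted p = 0.0768), apoptosis (0.0871), NADPH oxidase (0.417), MHC class II (0.417), primary granule (0.229), haematopoietic progenitor (0.517), immediate early and heat shock (0.16), plasma cell (0.0712), platelet (0.15), dendritic cell (0.838) and eosinophil, basophil and mast cell markers (0.793). T cell, NK and B cell markers were not called with all arrays (adjusted p = 0.451, 0.342 and 0.673). With WT replicate 2 left out, the T cell list was higher in KO than in WT cells by a median of 1.59, with 9 of 11 genes rising (adjusted p = 3.08e-06, and adjusted p = 0.201 with an estimated correlation). So were NK markers by 0.80 (adjusted p = 6.09e-05, and adjusted p = 0.293 with an estimated correlation). The B cell (adjusted p = 0.00522), plasma cell (0.000419) and eosinophil lists (0.00523) were then also higher, with adjusted p = 0.14, 0.14 and 0.201 with an estimated correlation. Median and test of the dendritic list differed in sign, as did median and mean of the B cell list. Of the aryl hydrocarbon receptor targets only 2 were measured, too few for a list test.

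In all, 218 of 10880 genes changed in KO vs WT, 128 higher and 90 lower, and 2061 had an unadjusted p under 0.05. The 3 arrays of each group did not overlap for 2547 genes (23.4%, where chance gives 10%). After WT replicate 2 was left out, 2177 genes changed, 1114 higher and 1063 lower, among them all 218. The count was 55, 51 and 45 without syngeneic replicates 1, 2 and 3, 48 and 64 without WT replicates 1 and 3, and 368, 33 and 41 without KO replicates 1, 2 and 3. More genes were lower than higher without KO replicate 1 (145 higher, 223 lower) and with array weights (1424 and 1542), while a fold threshold of 1 on the log2 scale left 51 higher and 9 lower. The fit on only the 6 arrays compared called 2 genes. Of the 34 named genes called, Tgm2 alone kept its call in every setting tried. Of 30 lists, 14 were called, and 0 with an estimated correlation, where limma's camera gave 6 at an unadjusted p under 0.05 and fry gave 10 after adjustment. KO arrays lay on their own chip, so chip and genotype cannot be told apart. The lack of Xist signal on the KO arrays leaves open that sex differed between the groups too. Sex then could not be told apart from genotype either.

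**Figure D3:**
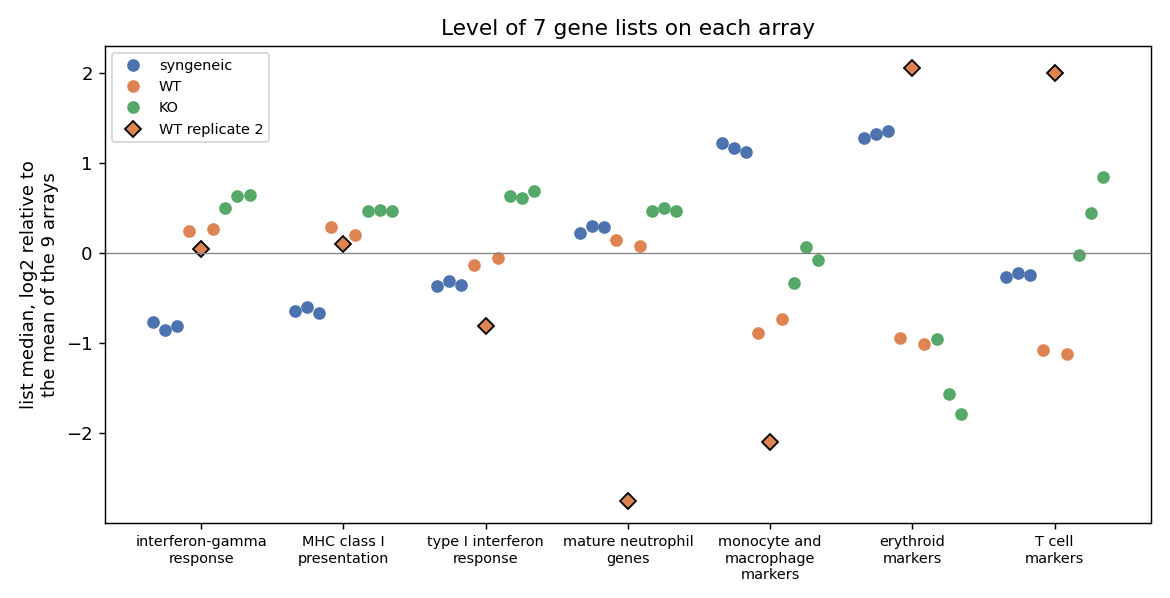
Median of the genes of 7 lists on each array, in log2 units relative to the mean of the 9 arrays (vertical axis); diamonds mark WT replicate 2. The type I interferon list lies between 0.61 and 0.69 on the KO arrays and at -0.13, -0.81 and -0.06 on WT replicates 1, 2 and 3, and the T cell list at 2.00 on WT replicate 2.

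WT vs syngeneic compared Gr-1+ cells of allogeneic hosts with IDO1 and of syngeneic hosts, and both groups shared a chip. Donor and host share a strain in a syngeneic transplant and not in an allogeneic one, so the strain of donors or of hosts differed here. Which of them differed was not examined. Differences of strain, also in how probes match polymorphic genes, cannot be told apart from the allogeneic reaction. Interferon-gamma targets rose as a list in WT cells, with 11 of 16 genes rising (camera adjusted p = 1.26e-07, and adjusted p = 0.103 with an estimated correlation). Cxcl9 and Cxcl10, chemokines that attract activated T cells, rose by 2.57 ± 0.38 (log2 fold change ± SE, n = 3, adjusted p = 0.00418) and 2.06 ± 0.52 (adjusted p = 0.0429; Cxcl10 rose by 2.72 without WT replicate 2). Gbp2 rose by 1.95 ± 0.10 (adjusted p = 1.66e-05) and Igtp, a GTPase induced by interferon, by 1.96 ± 0.17 (adjusted p = 0.000209). Among the largest falls, Spic fell by 4.31 ± 0.36 (adjusted p = 0.000204). Of the monocyte and macrophage markers 8 of 12 fell (list adjusted p = 0.334 with an estimated correlation). Among them, Vcam1 fell by 3.56 ± 0.22 (adjusted p = 3.34e-05) and C1qc, a further chain of C1q, fell by 3.55 ± 0.37 (adjusted p = 0.000666).

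The other largest rises in WT vs syngeneic were Ccl3, a chemokine that attracts inflammatory cells (2.56 ± 0.52), and H2-Q8 and H2-Q6, MHC class I genes outside the classical set (2.39 ± 0.10 and 2.34 ± 0.09). They also included Serpina3f, of the serpin protease inhibitor family (2.14 ± 0.11), Il12rb1, a chain of the interleukin-12 receptor (2.05 ± 0.17), and Psmb1, a proteasome subunit (2.01 ± 0.23). The H2-Q genes resemble each other closely, and how far their probes tell them apart was not examined. Among the falls, Alas2, which starts haem synthesis in red cell precursors, fell by 3.87 ± 0.88, and Trim10, a gene of erythroid maturation, fell by 3.62 ± 0.75. Plpp3, a lipid phosphatase, fell by 3.72 ± 0.26 and Ptgis, or prostacyclin synthase, fell by 3.69 ± 0.09. Apoe, a lipid carrier made by macrophages, fell by 3.50 ± 0.22, Igf1, a growth factor, fell by 3.45 ± 0.38 and Amy2a5 fell by 3.41 ± 0.42. Without WT replicate 2, which had the highest WT signals of both erythroid genes, Alas2 fell by 5.10 and Trim10 fell by 4.67. Adjusted p with all arrays for these 13 genes lay between 5.4e-07 for Ptgis and 0.0287 for Alas2.

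In the interferon-gamma list 11 of 16 genes rose and 0 fell in WT vs syngeneic, also adjusted over the list alone (13 and 0 without WT replicate 2), with a median of 1.03 (camera adjusted p = 1.26e-07, and adjusted p = 0.103 with an estimated correlation). MHC class I presentation had 10 of 13 genes rising (11 adjusted over the list alone, 12 without WT replicate 2) and a median of 0.89 (adjusted p = 3.09e-10), and it kept its call with an estimated correlation (adjusted p = 0.0198). Tap1, the partner of Tap2, rose by 1.37 ± 0.09, Nlrc5, the activator of MHC class I genes, by 1.36 ± 0.17 and Psmb9, an immunoproteasome subunit, by 1.02 ± 0.09. MHC class II presentation rose (9 of 14, 10 adjusted over the list alone, 9 with 2 falling without WT replicate 2; adjusted p = 0.000137, and adjusted p = 0.207 with an estimated correlation). H2-Aa, a class II chain, rose by 1.10 ± 0.22 and Ciita, the class II activator, by 1.04 ± 0.10, while Cd86, a costimulatory ligand, fell by 2.38 ± 0.19. The type I interferon list was not called (adjusted p = 0.833). Oasl1 rose by 0.51 ± 0.13 and Rsad2 fell by 1.75 ± 0.23, the same counts as adjusted over the list alone. The list's median (0.12) and mean (-0.02) differed in sign. It rose without WT replicate 2, with 12 genes up and 1 down (adjusted p = 0.012, and adjusted p = 0.481 with an estimated correlation). Oxidative phosphorylation rose (4 of 18, 5 adjusted over the list alone, 5 without WT replicate 2; adjusted p = 0.00744, and adjusted p = 0.441 with an estimated correlation). Cycs, or cytochrome c, rose by 0.65 ± 0.11. S phase genes (1 of 16, 2 adjusted over the list alone, 3 without WT replicate 2; adjusted p = 0.00744, and adjusted p = 0.687 with an estimated correlation) rose, and so did G2 and M phase genes (2 of 11, 4 adjusted over the list alone, 4 without WT replicate 2; adjusted p = 0.0339, and adjusted p = 0.511 with an estimated correlation). Neither the S phase nor the G2 and M phase list was called without WT replicate 2 (adjusted p = 0.155 and 0.0555). That array lay 0.54 above WT replicates 1 and 3 for S phase genes (median of the list). Gins2, a replication factor, rose by 0.54 ± 0.11 and Cdc20, a mitotic activator, by 0.37 ± 0.08. In the tryptophan-kynurenine pathway, not called as a list (adjusted p = 0.163), Wars rose by 1.21 ± 0.10 and Kyat3, a kynurenine aminotransferase, by 0.70 ± 0.11, and 4 of 8 rose adjusted over the list alone (3 rose and 1 fell over all genes without WT replicate 2).

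Monocyte and macrophage markers fell in WT vs syngeneic in 8 of 12 genes (10 adjusted over the list alone, 10 without WT replicate 2), with a median of -1.98 (camera adjusted p = 2.54e-09, and adjusted p = 0.334 with an estimated correlation). Mrc1, the mannose receptor, fell by 3.38 ± 0.36, Csf1r, the receptor macrophages need to survive, by 2.05 ± 0.41 and Marco, a scavenger receptor, by 1.56 ± 0.12. Hmox1, which breaks down haem, fell by 3.12 ± 0.45, and without WT replicate 2 fell by 2.51. Erythroid markers fell as a list (1 of 12, 2 adjusted over the list alone; adjusted p = 0.0186, and adjusted p = 0.711 with an estimated correlation). WT replicate 2 held high erythroid signals, and without it 12 of 12 fell with a median of -2.02 (adjusted p = 1.04e-12, and adjusted p = 0.119 with an estimated correlation). Secondary granule and mature neutrophil lists fell with 0 of 13 and 0 of 16 genes falling, also adjusted over the list alone, and 1 and 0 at an unadjusted p under 0.05 in limma (camera adjusted p = 0.0111 and 0.039, and adjusted p = 0.711 and 0.772 with an estimated correlation). These calls ended without WT replicate 2 (0.374 and 0.446), as did those of the S phase (0.155) and G2 and M phase lists (0.0555). Without that array 2 granule and 5 neutrophil genes fell, and 1 and 2 rose. The mature neutrophil call also ended without syngeneic replicate 2 (0.0724), KO replicate 1 (0.0515) or KO replicate 3 (0.0604). The G2 and M phase call further ended without syngeneic replicate 2 (0.0683), WT replicate 1 (0.0596) or WT replicate 3 (0.0917), and the erythroid call without WT replicate 1 (0.167) or 3 (0.189) and in the fit with detection p-values (0.0905). Array weights ended the granule (0.421), mature neutrophil (0.569) and S phase calls (0.14). The stricter probe filter ended the mature neutrophil (0.0679) and G2 and M phase calls (0.0544). The former also ended on the 6 arrays alone (0.0733), and the latter without background correction (0.0521) and with the series matrix values (0.0581). T cell, NK and B cell markers were not called (adjusted p = 0.657, 0.657 and 0.603). Once WT replicate 2 was left out, T cell markers were lower in WT than in syngeneic cells (6 of 11 fell, median -0.78; adjusted p = 0.012, and adjusted p = 0.481 with an estimated correlation). B cell (0.00465), plasma cell (0.00513), dendritic (0.012) and platelet markers (0.00298) were then also lower, and primary granule (0.0382) and IL-6 and STAT3 genes (0.0206) higher. With an estimated correlation the adjusted p of these 6 lists were 0.112, 0.112, 0.137, 0.232, 0.296 and 0.141. Platelet markers were also called without syngeneic replicate 2 (0.0486). Ccr3, the eotaxin receptor, fell by 2.10 ± 0.13 and Vwf, a clotting protein of platelets and vessel walls, by 1.90 ± 0.19 within lists that were not called (adjusted p = 0.73 and 0.0936). For the former list, fry gave the opposite sign to camera and the median.

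In all, 1135 genes changed in WT vs syngeneic, 522 higher and 613 lower, with 2948 at an unadjusted p under 0.05 and 4190 (38.5%, where chance gives 10%) whose groups did not overlap. The within-chip fit on the 6 arrays gave 698, and a fold threshold of 1 on the log2 scale left 61 higher and 268 lower. The count was 3215 without WT replicate 2, 1591 higher and 1624 lower, including all 1135. It was 511, 516 and 485 without syngeneic replicates 1, 2 and 3. Of the lists, 10 were called, 8 by fry and 1 with an estimated correlation.

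KO vs syngeneic set the allogeneic hosts without IDO1 against the same controls. The strain of donors or of hosts differed here too, and so did the chip. Of the interferon-gamma targets 13 of 16 rose. The list was also called with an estimated correlation (adjusted p = 0.0313), but with that correlation not once WT replicate 2 was left out (adjusted p = 0.109). Cxcl10 rose by 3.66 ± 0.52 (log2 fold change ± SE, n = 3, adjusted p = 0.00301) and Cxcl9 by 3.20 ± 0.38 (adjusted p = 0.00131). Outside that list, Serpina3f rose by 3.26 ± 0.11 (adjusted p = 2.92e-06), Gbp2b, a guanylate-binding GTPase, rose at least 8.80-fold (adjusted p = 1.05e-05), and Rab15, a trafficking GTPase, by 3.08 ± 0.53 (adjusted p = 0.00736). Of the erythroid markers 5 of 12 fell (list adjusted p = 8.93e-06, and adjusted p = 0.46 with an estimated correlation). Slc4a1, the red cell anion exchanger, fell by 6.89 ± 1.17 (adjusted p = 0.00715) and Alas2 fell by 5.67 ± 0.88 (adjusted p = 0.00465). Outside that list, Trim10 fell at least 30.2-fold (adjusted p = 0.00349), Aqp1, a water channel, fell by 4.69 ± 1.26 (adjusted p = 0.0485) and Apol11b, of the apolipoprotein L family, fell by 5.37 ± 1.02 (adjusted p = 0.0117).

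In the interferon-gamma list 13 of 16 genes rose and 0 fell in KO vs syngeneic (13 and 1 adjusted over the list alone, 14 and 1 without WT replicate 2), with a median of 1.44 (adjusted p = 4.61e-12, and adjusted p = 0.0313 with an estimated correlation). Without WT replicate 2 the latter was 0.109. MHC class I presentation rose in 11 of 13 genes, also adjusted over the list alone (12 without WT replicate 2), with a median of 1.13 (adjusted p = 1.62e-14, and adjusted p = 0.00763 with an estimated correlation). Type I interferon genes rose in 12 of 19 (15 adjusted over the list alone, 16 with 1 falling without WT replicate 2; median 0.96; adjusted p = 1.18e-09, and adjusted p = 0.418 with an estimated correlation). Oasl1 rose by 1.87 ± 0.13 and Isg15 by 1.68 ± 0.14. MHC class II presentation rose in 8 of 14 (10 adjusted over the list alone, 11 without WT replicate 2; adjusted p = 1.99e-05, and adjusted p = 0.15 with an estimated correlation), while Cd86 fell by 1.82 ± 0.19. Glycolysis rose (2 of 15, also adjusted over the list alone, 7 with 1 falling without WT replicate 2; adjusted p = 0.0227, and adjusted p = 0.265 with an estimated correlation). Pfkp, a phosphofructokinase, rose by 0.99 ± 0.12. Primary granule genes rose (2 of 11, also adjusted over the list alone, 4 without WT replicate 2; adjusted p = 0.0342, and adjusted p = 0.46 with an estimated correlation). Ms4a3, a gene of granulocyte precursors, rose by 0.84 ± 0.12. Immediate early and heat shock genes, which cell handling can induce, rose too (2 of 13, 4 adjusted over the list alone, 6 without WT replicate 2; adjusted p = 0.0342, and adjusted p = 0.418 with an estimated correlation). Egr1, an immediate early transcription factor, rose by 1.08 ± 0.21. Without syngeneic replicate 1 both calls ended (0.051 and 0.0633), the granule call also without KO replicate 1 (0.143) and the heat shock call without KO replicate 3 (0.123). With the mean of a gene's probes the glycolysis, heat shock and granule calls ended (0.0661, 0.0661 and 0.0726). The heat shock and granule calls further ended with the series matrix values (0.138 and 0.0556), the stricter probe filter (0.0588 and 0.0509) and the fit with detection p-values (0.107 and 0.0604). No background correction ended the heat shock call (0.0779) and array weights the granule call (0.0537).

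Macrophage markers fell in 7 of 12 genes in KO vs syngeneic (9 adjusted over the list alone, 10 with 2 rising without WT replicate 2; median -1.46; adjusted p = 1.99e-05, and adjusted p = 0.418 with an estimated correlation). Vcam1 fell by 2.35 ± 0.22 and C1qc fell by 1.75 ± 0.37. Erythroid markers fell in 5 of 12 (10 adjusted over the list alone, 12 without WT replicate 2; median -2.65; adjusted p = 8.93e-06, and adjusted p = 0.46 with an estimated correlation). Hba-a1, a haemoglobin chain, fell by 3.74 ± 0.77; without KO replicate 1 it fell by 4.53 and without KO replicate 3 it fell by 3.02. Platelet markers fell in 3 of 7, also adjusted over the list alone, and in 6 with 1 rising without WT replicate 2 (adjusted p = 0.00368, and adjusted p = 0.418 with an estimated correlation), with Vwf down (log2 fold change -1.84 ± 0.19). T cell markers had a median of 0.75 and were not called (adjusted p = 0.283). Without WT replicate 2, 8 of 11 rose (adjusted p = 0.0188, and adjusted p = 0.488 with an estimated correlation). Starvation response (0.0357), mature neutrophil (0.0357) and IL-6 and STAT3 genes (0.0185) were then also higher and dendritic markers (0.0357) lower. With an estimated correlation the adjusted p of these 4 lists were 0.364, 0.217, 0.148 and 0.217. Median and test of the antioxidant, kynurenine and eosinophil lists, none of them called, differed in sign.

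In all, 1298 genes changed in KO vs syngeneic, 553 higher and 745 lower, with 2809 at an unadjusted p under 0.05 and 5365 (49.3%, where chance gives 10%) whose groups did not overlap. The count was 4270 without WT replicate 2, 2099 higher and 2171 lower, including all 1298, and the fit on the 6 arrays compared called 4000. The fold threshold left 124 higher and 254 lower. The count was 660, 683 and 649 without syngeneic replicates 1, 2 and 3, and 740 and 759 without KO replicates 2 and 3. Of the lists 10 were called, 12 by fry and 2 with an estimated correlation. In the same direction in WT vs syngeneic and KO vs syngeneic, 693 genes changed, 258 higher and 435 lower, and 4 changed in opposite directions. Independent lists would share 26.5 and 42.0. In 100 simulations of unchanged groups against shared controls the mean was 0.01 and the highest count 1. Unchanged groups give few calls to share, so these simulations cannot size the effect of shared controls when many genes are called. Part of the excess may come from the shared controls, which are too few to split. The shared count was 2164 without WT replicate 2, and 370, 370 and 344 without syngeneic replicates 1, 2 and 3.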

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

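Tests chosen only after the result was seen were that of exchanged labels, the 3 on the interferon genes, and the count of probes lost on the KO arrays at 3 signal limits. Of the probes with a deposited detection p of 0 in all 9 columns, 752 had a mean signal under 10; of the fits, only the alternative that follows the first design uses these p-value columns. A p of 0 in all columns was found for 12 of 15 intestinal epithelium genes, of which 3 had a signal above the limit, and for 0 of 10 liver, 4 of 7 brain and 0 of 7 muscle and heart genes, against 3 of 11 primary granule and 1 of 16 mature neutrophil genes, all of which had signals above the limit. Mpo, or myeloperoxidase, had p-values from 0.17 to 0.919 at signals of 26521 to 31053.

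WT replicate 2 stood apart from WT replicates 1 and 3. Exchange of labels with another group is argued against by its highest correlation with any array, 0.924, which lay below the lowest among the other 8, 0.966, though an exchange with an outside sample stays open. Random noise of the array is argued against by a correlation of 0.814, across 4253 genes, which are not independent replicates, between the difference of this array from WT replicates 1 and 3 at the brightest probe and that at the second brightest; RNA quality was not tested. A larger share of T and erythroid cells may account for it. Sets of other T cell genes (8 of 9 tested) and erythroid genes (3 of 7 tested) were written down before their values were seen. Their medians lay 3.73 and 3.16 above WT replicates 1 and 3. The fixed lists of both cell types were already high on this array, so these sets could hardly come out otherwise and add little. Cd3e, a T cell receptor chain, was at 9082 against 350 and 347. Car1, a red cell carbonic anhydrase, was at 14276 against 397.9 and 349.2. Cells were isolated for Gr-1, yet genes of both cell types also gave signal on the syngeneic arrays. Cd3e was at 875.4, 913 and 938.6 there and Slc4a1 at 18398.8, 19772.8 and 19394.7. The shift of WT replicate 2 was not limited to T and erythroid genes. Against WT replicates 1 and 3, its medians were 2.15 for NK markers (9 of 9 genes above 0) and 1.36 for B cell markers (5 of 5). They were 1.94 for eosinophil, basophil and mast cell markers (6 of 7) and 1.37 for dendritic markers (3 of 5). Its macrophage list was lower (-1.47). What would raise the share of any of these cells in WT replicate 2 was not tested.

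The KO arrays lacked Xist signal and had signal for Eif2s3y, a Y-linked gene, at 37, 111 and 54 by its probe that was below 0 on the other arrays, while the other Eif2s3y probe did not separate the groups, Kdm5d reached only 10.4, 15.1 and 7.7 by 1 of its probes, and the probes of Usp9y, Zfy1 and Zfy2 stayed at background on all arrays. Of 4 Uty probes 3 stayed at background too, 1 of them lowest in KO (-14.3, -15.4 and -11), and the other lay at 12.4 to 15.5 in syngeneic, 18.3 to 23.8 in WT and 13.4 to 27.2 in KO. A loss of probes of any gene on the KO chip is argued against: at signal limits of 50, 100 and 200, the number of probes of other genes above the limit on each of the 6 other arrays and lost on all 3 KO arrays was 0, against 3, 2 and 2 Xist probes. A broader chip difference stays open, since the KO arrays lay on their own chip. Of 5081 other probes of similar mean brightness, 13 (0.256%) were lost in KO, between the bounds set beforehand. These 13 had signals of at most 20.7 in WT replicates 1 and 3 on the other chip too, so their loss is no sign of a chip difference. Cells of male mice in KO and of female mice in the other groups may account for the pattern: the 4 X-linked genes known to escape inactivation had medians of -0.37 in KO vs WT and -0.46 in KO vs syngeneic, a test written beforehand, though of these only Kdm6a in KO vs syngeneic passed (adjusted p = 0.0388); sex then could not be separated from genotype in any KO comparison.

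Of 19 type I interferon genes 7 rose in KO vs WT, with a median of 0.94 (0.70 without WT replicate 2) and a list adjusted p = 0.227 with an estimated correlation, and a chip difference cannot be told apart from genotype here. A larger share of T cells may contribute, but WT replicate 2, highest in T cell markers, had a median of -0.69 against WT replicates 1 and 3, which as 1 array excludes nothing. From KO replicate 1 to 3, Cd3e rose (1072.2, 1652.5 and 2787.8). Of the 7 interferon genes called, all but Stat2 (667.2, 632.6 and 627.4) rose in the same order. So few arrays cannot decide it. More macrophages may contribute too. The list was 0.96 higher in KO than in syngeneic cells, whose macrophage markers were higher, which leaves open macrophages that respond only in allogeneic hosts. Cells were isolated for Gr-1, yet macrophage and T cell genes gave signal. Vcam1 had means of 17341 in syngeneic and 3366 in KO cells, and Thy1 had 2942.8, 3790.2 and 5330.4 on the KO arrays. An effect of IDO1 loss, or of sex, stays open as untested.

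With 10 splits of 6 arrays a share under 0.05 cannot be reached. The real split called 218 genes in KO vs WT (highest other 6, where the limma fit gave up to 1742 at an unadjusted p under 0.05 against 2061 in the real split), 1135 in WT vs syngeneic (0, with up to 820 unadjusted) and 1298 in KO vs syngeneic (0, with up to 184 unadjusted), each reached in 1 of the 10. For lists, 14 in KO vs WT (highest other 13, lowest 4) were reached in 1 split, 10 in WT vs syngeneic (17) in 5 and 10 in KO vs syngeneic (10) in 4.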

How the results depend on the processing

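The offset of 16 and the limits replacing the planned probe filters were chosen after seeing the data, as was making the first design, the fit with the deposited detection p-values, an alternative. The counts of changed genes, 218 in KO vs WT, 1135 in WT vs syngeneic and 1298 in KO vs syngeneic, moved with several choices, and except as stated the cause was not tested. Array weights, which gave WT replicate 2 a weight of 0.0415, called 2966, 4370 and 4588 genes and raised the shared count of 693 to 2543. The fits on only the 6 arrays compared gave 2, 698 and 4000; the last leaves WT replicate 2 out by construction. A fold threshold of 1 on the log2 scale, which only removes genes, left 60, 329 and 378, and 241 shared. KO vs WT gave 139 without background correction and 95 with the series matrix values, whose list tests used genes without missing values. With the detection p-values of the first design the counts were 249, 975 and 1153. Leaving out 1 array gave 33 to 2177 genes in KO vs WT, 485 to 3215 in WT vs syngeneic, 649 to 4270 in KO vs syngeneic and 344 to 2164 shared. Lists called fell from 14, 10 and 10 to 0, 1 and 2 with an estimated correlation, where camera gave 6, 4 and 4 at an unadjusted p under 0.05. Kit, a growth factor receptor that did not pass in KO vs WT (log2 fold change -0.73, adjusted p = 0.633), ranged from -1.27 to 0.33 when 1 array was left out, with an adjusted p of 0.0217 at 0.33, without WT replicate 2. Ido1 in KO vs WT had a log2 fold change of -0.55 and adjusted p from 0.0013 to 0.203 over the alternatives, with a fold change of -1.38 without background correction, -1.01 with an offset of 16 and -0.0045 in the fit with detection p-values, and no value with the stricter filter or the series matrix. Dim genes like it are limited by signal over background. Named genes called all kept their direction (34, 62 and 70), and 1, 37 and 34 kept their call in every setting. The groups of every called gene did not overlap, so leaving out 1 array could not turn its direction.

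With the replicate number as a block the counts were 31 in KO vs WT, 717 in WT vs syngeneic and 903 in KO vs syngeneic, and Ido1 was not called in KO vs WT (adjusted p = 0.102). The numbers do not pair the arrays: of 9 same-numbered pairs 1 had a correlation of deviations over 0.1, with a range of -0.17 to 0.11, and 2 of the 9 arrays correlated best with their own number.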

Other observations

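The genes given here were chosen after their values were seen. Among genes of lists that the text has not yet described, Casp1, the caspase that activates interleukin-1, rose by 0.66 ± 0.13 in KO vs syngeneic (log2 fold change ± SE, n = 3, adjusted p = 0.0145) and Bak1, a pro-apoptotic membrane protein, by 1.16 ± 0.18 (adjusted p = 0.00496) and in WT vs syngeneic by 0.78 ± 0.18 (adjusted p = 0.0315). Ppp1r15a, which reverses the block on translation under stress, fell by 2.66 ± 0.40 in KO vs syngeneic (adjusted p = 0.00392) and by 2.04 ± 0.40 in WT vs syngeneic (adjusted p = 0.0156). Psat1 and Phgdh, enzymes of serine synthesis, rose by 0.76 ± 0.20 and 0.84 ± 0.22 in KO vs syngeneic (adjusted p = 0.0461 and 0.0405) and by 0.95 ± 0.20 and 0.93 ± 0.22 in WT vs syngeneic (adjusted p = 0.0227 and 0.031). Sod2, the mitochondrial superoxide dismutase, rose by 0.72 ± 0.14 in KO vs syngeneic (adjusted p = 0.0114). Klrk1, the activating receptor NKG2D, rose by 0.71 ± 0.17 (adjusted p = 0.033). In WT vs syngeneic the log2 fold changes of Casp1, Sod2 and Klrk1 were 0.14 ± 0.13, 0.48 ± 0.14 and 0.50 ± 0.17 and did not pass (adjusted p = 0.515, 0.0623 and 0.108).

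Lymphocyte and erythroid markers differed between arrays of a group. Cd3e had signals of 1072, 1652 and 2788 on the KO arrays, 350, 9082 and 347 on WT replicates 1, 2 and 3, and 875.4, 913 and 938.6 on the syngeneic arrays. Thy1, a T cell surface protein, had signals of 2943, 3790.2 and 5330.4 on the KO arrays, 915.4, 17266.5 and 934.1 on WT replicates 1, 2 and 3, and 2468 to 2687 on the syngeneic arrays. Slc4a1 had signals of 250.6, 68.5 and 32.4 on the KO arrays, 305.1, 9962 and 284.4 on WT replicates 1, 2 and 3, and 18399 to 19773 on the syngeneic arrays. Ltf, or lactoferrin, an abundant neutrophil granule protein, lay between 32799 and 38407 on the 8 arrays other than WT replicate 2, where it was 8741.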
